A study of Rattus norvegicus with 12 samples.

How the data were processed

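Poly(A) RNA was profiled from 6 rats in laser-captured tissue of the dorsal horn of the spinal cord (SC) and of the trigeminal nucleus caudalis (TNC), with 1 library per region and rat. Per the labels' protocols, the perfused tissue was frozen, sectioned and stained, RNA was extracted from the captured pieces, and the libraries were sequenced on an Illumina HiSeq instrument. How the borders of the captured areas were drawn is not given in the sources used here. Each deposited file holds raw read counts per gene of 1 library, whole numbers with no sign of normalization in their totals, with HTSeq's summary lines at the end. STAR, an aligner of spliced reads, and HTSeq, which counts reads per gene, are named in the submitters' processing notes. Their versions and settings, the strand setting, the genome build and the annotation release are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart. HTSeq's default leaves out reads that align to several places, so genes with near-identical copies are under-counted if that default was used.

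The 32662 gene identifiers are Ensembl rat identifiers. The gene table at hand (RefSeq, assembly GRCr8) pairs none of them with a symbol: 0 identifiers matched. The 34 gene lists fixed before the data were examined, the gene list tests, the share of reads on mitochondrially encoded genes, and the part of the naming rule that needs symbols were therefore not run. Gene positions, lengths and GC content were not used here. The naming rule, fixed before the data were examined, took the genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 1 CPM over all libraries and the same direction in all 6 rats. After the data were seen it was applied without its requirement of a symbol, which no gene met, and the first 2 genes per direction are printed by identifier.

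HTSeq's summary lines were left out of library sizes and tests. Reads outside annotated genes made up 14.999% of alignments in SC and 13.2% in TNC on average. Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 13833 genes holding 99.9% of the gene reads, and libraries were scaled by trimmed mean of M values (TMM). Differences were tested with edgeR's quasi-likelihood test (glmQLFit without the legacy option and glmQLFTest) on a model of rat plus region over all 12 libraries, which leaves 5 residual degrees of freedom per gene. P-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. The rat is the replicate, and the pairing comes from the rat number in the library titles and from the stated capture of both regions in each rat. As a check of the pairing, deviations from the region means were correlated between regions: they correlated between 0.14 and 0.20 for libraries of the same rat and at most 0.05 for libraries of different rats, and all 12 libraries correlated best with their own rat's other library.

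CPM are counts scaled to a common library size with TMM factors. Log2 CPM used a prior count of 2. The printed standard errors are those of the 6 within-rat ratios of log2 CPM. At low counts the prior count shrinks these ratios, so they are smaller than the fitted log2 fold changes. Intervals of the difference came from limma voom with the rat as a block. Ratios for genes with 1 to 3 reads in a region are pooled normalized reads with an exact (Clopper-Pearson) counting interval, and a region with 0 reads was set to a floor of 3 reads over its 6 libraries. Library measures were compared by exact two-sided sign-flip permutation tests of the 6 within-rat differences (64 sign patterns). Of the 7 measures, 3 (total reads, genes detected, share of the 10 most abundant genes) were chosen before the data were examined, and those from HTSeq's summary lines and the thinned gene number afterwards. Counting error on shares of alignments was small: the widest 95% Wilson interval of a share outside annotated genes spanned 0.0346 percentage points. Libraries of the same region differed by more than sampling noise in every pair (chi-square per degree of freedom between 6.67 and 20.9), so none was treated as a duplicate.

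The tests were first checked on simulated counts with 200 genes changed by known folds, drawn from the real genes' means, dispersions and library sizes. Alternatives fixed before the data were examined were edgeR's relative log expression (RLE) and upper-quartile scaling, no filter and a filter of 1 CPM in 6 libraries, DESeq2, limma voom, edgeR's legacy quasi-likelihood fit, no block, and each rat left out in turn. Alternatives chosen after seeing the data were thinning to equal totals, the share of alignments outside annotated genes as a covariate, and rats R101 to R103 and R104 to R106 alone. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.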

Results

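Gene expression was measured by poly(A) RNA sequencing in 2 regions of the central nervous system that receive primary sensory afferents. The trigeminal nucleus caudalis (TNC) lies in the caudal medulla and receives pain and temperature input from the face and the meninges. The dorsal horn of the spinal cord (SC) receives the corresponding input from the body. Both regions were captured by laser microdissection from each of 6 untreated male rats of the outbred Wistar Han strain, aged 10 weeks, which gave 12 libraries in 6 within-animal pairs. The libraries held between 11223405 and 14591508 reads assigned to genes, and between 16449 and 17536 genes were detected with at least 1 read. The comparison implied by the design is that of TNC with SC within rats, and positive log2 fold changes denote higher expression in TNC. The files identify genes by Ensembl rat identifiers only, and none of the 32662 identifiers could be paired with a symbol here, so expression is described by numbers of genes and by 4 identifiers, 2 for each direction. The gene families, transmitter systems and cell types to which the differing genes belong were therefore not analysed here.

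The profiles of both regions were similar in general and separated completely by region. Across the 13833 genes with sufficient reads, the median Pearson correlation of log2 CPM, counts scaled by library size, was 0.978 between libraries of the same region and 0.963 between libraries of different regions. These correlations are across genes, which are not independent replicates. The first principal component held 36.1% of the variance and parted the regions without overlap, with scores from 18.9 to 38.5 in the TNC libraries and from -30.5 to -20.6 in the SC libraries. The second component held 10.4% of the variance and parted the same sets of rats in both regions. On this component the TNC libraries of rats R101, R102 and R103 scored between -29.6 and -7.30 and those of rats R104, R105 and R106 between 19.3 and 22.7. The SC libraries of the same sets of rats scored between -12.9 and -4.79 and between 0.697 and 4.21, a narrower range.

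**Figure D1:**
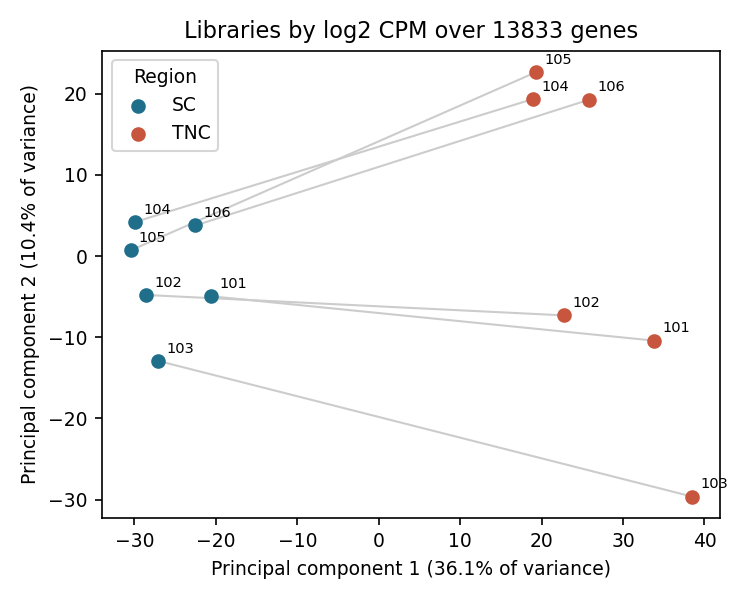
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, in arbitrary units, with a point per library, colour for region and a grey line joining the libraries of each rat. TNC lies between 18.9 and 38.5 on the first component and SC between -30.5 and -20.6, and rats R101 to R103 lie below rats R104 to R106 on the second.

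Of the 13833 genes tested, 4192 (30.3%) differed between TNC and SC at an adjusted p under 0.05 (edgeR quasi-likelihood test with the rat as a block, Benjamini-Hochberg adjustment). With TMM scaling 2072 genes were higher in TNC and 2120 higher in SC, and with upper-quartile scaling 1754 and 2432. Most differences were small: the median change among the 4192 genes was 1.32-fold, and 3740 of them (89.2%) differed by less than 2-fold. The direction was the same in all 6 rats for 3118 of the 4192 genes (74.4%), which a test with the rat as a block favours. Expression ranges of both regions did not overlap at all for 701 genes higher in TNC and 766 higher in SC, together 10.6% of the tested genes. For a single gene, at most 3.12% of the exchanges of regions within rats part the regions. This value was calculated and not taken from exchanged data. It bounds the average share by chance, which correlated genes can exceed in a single exchange. For 8958 genes (64.8%) the 95% interval of the difference lay within 1.5-fold in either direction, and for 12084 genes (87.4%) it lay within 2-fold (limma voom, rat as a block).

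The share of genes that differed increased with expression level. It was 13.1% of the 206 tested genes below 1 CPM, 20.5% of the 4087 genes between 1 and 10 CPM, 31.2% of the 7530 genes between 10 and 100 CPM, and 48.5% of the 2010 genes above 100 CPM. On counts simulated for this comparison, run on 13725 genes, the same test recovered 65.2% of genes changed by 1.5-fold, 94.0% of those changed by 2-fold and 100% of those changed by 4-fold, and 6.52% of its calls were false. Only 200 genes were changed in the simulation, against 4192 called in the real data, so the adjusted threshold was stricter in the simulation. The recovered shares therefore do not measure what was detectable in the real comparison.

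Large differences were predominantly genes higher in SC. Among the 452 genes that differed by 2-fold or more, 372 were higher in SC and 80 higher in TNC, an SC share of 82.3% (exact binomial interval 78.5% to 85.7%, which treats genes as independent). At 4-fold or more there were 80 genes higher in SC and 12 higher in TNC. Of the 452 genes, 361 changed in the same direction in all 6 rats. The 372 SC-enriched genes were mostly of low abundance: 269 had a mean between 1 and 10 CPM, 78 between 10 and 100 CPM, and 4 above 100 CPM. Together they took 0.856% ± 0.104 (SD, n = 6) of the gene reads in SC and 0.246% ± 0.0405 in TNC. Of the 80 TNC-enriched genes, 50 had a mean between 1 and 10 CPM, 20 between 10 and 100 CPM, and 4 above 100 CPM. The 80 genes together took 0.223% ± 0.0283 (SD, n = 6) of the gene reads in TNC and 0.0806% ± 0.00591 in SC.

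**Figure D2:**
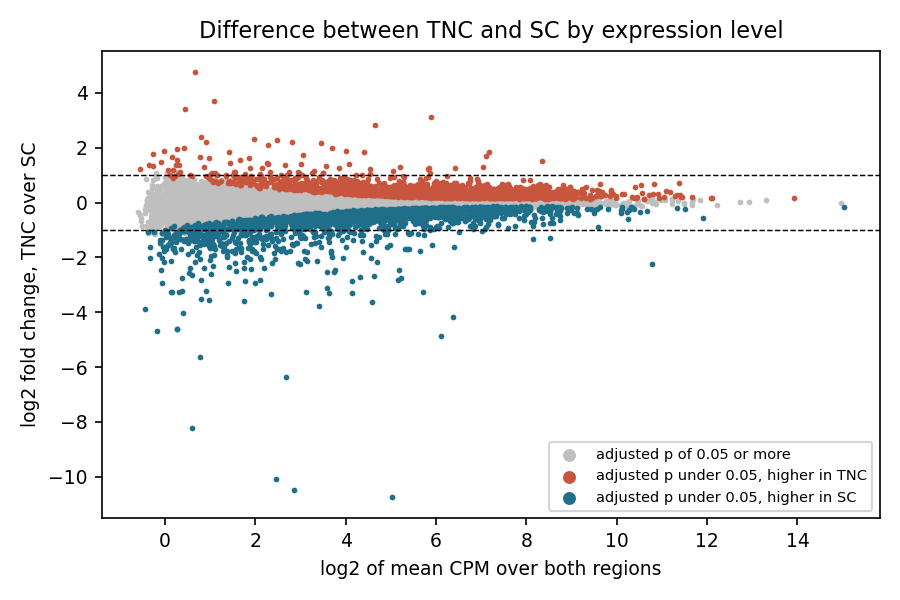
The log2 fold change of TNC over SC (y axis) against the log2 mean CPM over both regions (x axis), with a point per tested gene, coloured where the adjusted p was under 0.05, and dashed lines at 2-fold. Beyond the dashed lines 372 coloured genes lie on the SC side and 80 on the TNC side.

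Expression restricted to a single region was rare and was found in SC. With at least 10 reads in each of the 6 libraries of one region and at most 3 reads in all 6 libraries of the other, 4 genes were restricted to SC and none (0) to TNC. Among genes with a mean of at least 1 CPM, the gene with the largest fitted decrease in TNC was ENSRNOG00000028619. It had 65.2 ± 4.05 CPM (SD, n = 6) in SC, from 747 to 973 reads per library, and 2 reads over all 6 TNC libraries. The ratio of its pooled, normalized reads, SC over TNC, was 2298, with an exact counting interval from 636 to 18976. ENSRNOG00000016149 had 14.4 ± 5.60 CPM (SD, n = 6) in SC, from 88 to 291 reads per library, and 0 reads in the TNC libraries. Set against a floor of 3 reads over the whole TNC group, it was 343-fold higher in SC. The exact two-sided counting interval of its pooled ratio had a lower limit of 279 and no upper limit. Which of both genes had the larger decrease is therefore not settled. The adjusted p was 7.36e-15 for ENSRNOG00000028619 and 5.67e-09 for ENSRNOG00000016149 (edgeR), and both were higher in SC in 6 of 6 rats. These counting intervals and floors cover counting error only.

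The genes most enriched in TNC, by the same minimum of 1 CPM, had reads in some SC libraries. ENSRNOG00000010551 had 3.05 ± 1.06 CPM in TNC and 0.0977 ± 0.104 CPM in SC (SD, n = 6), with 20 to 53 reads per TNC library and 0 to 4 reads per SC library. Its log2 fold change was 4.76 with a standard error of 0.37 over the 6 within-rat ratios (adjusted p = 4.17e-08, edgeR). ENSRNOG00000023340 had 3.98 ± 2.01 CPM in TNC and 0.287 ± 0.340 CPM in SC (SD, n = 6), with 13 to 80 and 0 to 11 reads per library, respectively. Its log2 fold change was 3.70 with a standard error of 0.59 (adjusted p = 1.27e-06, edgeR). Both were higher in TNC in 6 of 6 rats, and their fold changes rest on 8 and 23 reads in all SC libraries. The size of both varied with the rats included. The log2 fold change of ENSRNOG00000010551 was 5.43 without rat R106, 6.76 in rats R101 to R103 alone and 3.57 in rats R104 to R106 alone. That of ENSRNOG00000023340 was 4.39 without rat R104, 5.59 and 2.34 in the same sets of rats, and 4.33 with DESeq2. In SC, rats R101, R102 and R103 had 1, 0 and 0 reads of ENSRNOG00000010551 and 4, 0 and 0 of ENSRNOG00000023340. Rats R104, R105 and R106 had 2, 1 and 4 reads and 11, 1 and 7 reads, respectively. With so few reads, counting error alone can move these values, and whether the rats differ was not tested.

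**Figure D3:**
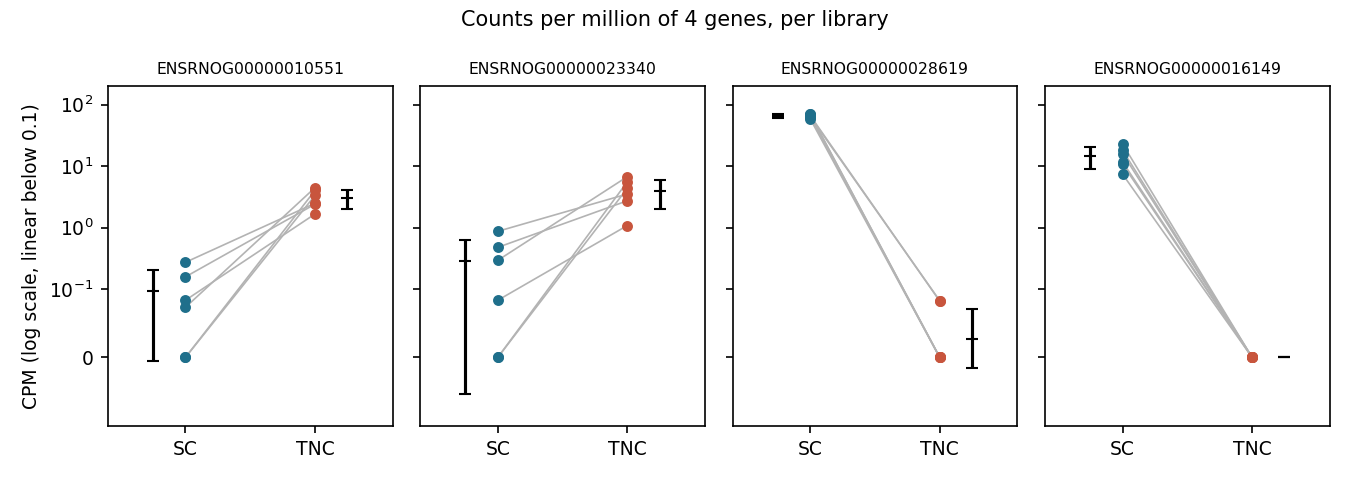
CPM (y axis, log scale, linear below 0.1) of the 4 genes in SC and TNC, with a point per library, a grey line per rat, and the mean with SD beside each group (n = 6). The first and second genes are higher in TNC in each rat, and the third and the last reach at most 1 read in any TNC library.

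Library composition also differed between the regions. Alignments outside annotated genes made up 14.999% ± 0.489 of all alignments in SC and 13.2% ± 1.03 in TNC (SD, n = 6), a mean within-rat difference of -1.84 percentage points with an SD of 0.692. It was lower in TNC in 6 of 6 rats (exact two-sided sign-flip permutation test, p = 0.0312, the smallest p that 6 pairs allow, adjusted p = 0.0437 over 7 library measures). The difference was -0.467 percentage points in rat R102 and averaged -2.11 in the other rats. Fewer genes were detected in TNC, 16869 ± 227, than in SC, 17340 ± 102.6 (SD, n = 6), again in 6 of 6 rats (exact permutation p = 0.0312, adjusted p = 0.0437). The 7 measures of the adjustment include those chosen after the data were examined, each at the smallest possible p. These lower the adjusted p of the genes detected, which therefore does not hold for the planned measures alone. The mean difference was -407 genes after the libraries were thinned to equal totals. Alignments to several places and alignments with an ambiguous gene were also less frequent in TNC in 6 of 6 rats (each exact permutation p = 0.0312), at 13.02% against 13.6% and 1.55% against 1.67%. Total reads on genes were 11884968 ± 376326 in TNC and 12755766 ± 1096420 in SC (exact permutation p = 0.0625, n = 6). They were lower in TNC in 5 of 6 rats, with a mean difference of -870798 reads, so equal depth was not shown. The share of reads in the 10 most abundant genes was 12.1% ± 1.22 in TNC and 12.6% ± 0.716 in SC (exact permutation p = 0.438, n = 6).

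**Figure D4:**
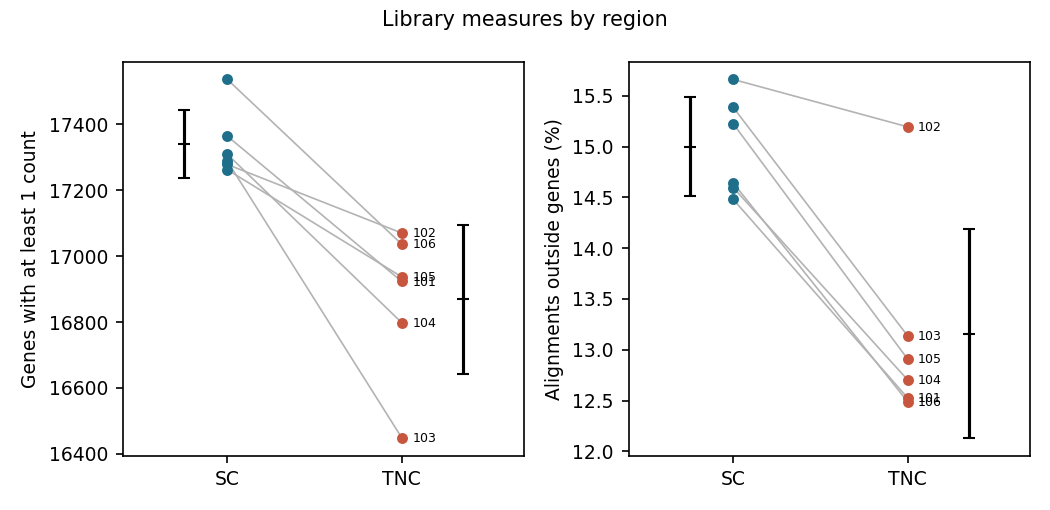
Number of genes with at least 1 read (left, y axis, not starting at 0) and percentage of alignments outside annotated genes (right, y axis, not starting at 0) in SC and TNC, with a point per library, a grey line per rat, and the mean with SD (n = 6). Both measures are lower in TNC in every rat, and rat R102 shows the smallest difference in alignments outside genes, -0.467 percentage points.

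The share of alignments outside annotated genes moved with region and was therefore entered as a covariate beside the rat. In that fit 64 genes differed, 16 higher in TNC and 48 higher in SC, of which 54 differed by 2-fold or more (edgeR). The covariate and the region were nearly collinear, with a 9.47-fold inflation of the variance of the region term. They were told apart mainly by rat R102, with a gap between regions of -0.467 percentage points against -1.89 to -2.32 in the other rats. The values of this fit therefore rest largely on 1 rat. The median size of the log2 difference among the 4192 genes was 0.40 before and 0.31 after. The median standard error, taken from limma voom, was 0.09 before and 0.28 after. Among the 452 genes with differences of 2-fold or more the median size was 1.41 before and 1.58 after, and the median standard error 0.30 before and 0.94 after. These sizes are absolute values, which a larger error raises. They therefore do not show that the differences held or grew. Of these 452 genes, 420 kept their direction. Among the 4 genes printed above, ENSRNOG00000028619 remained past the threshold in that fit and the other 3 did not, with fitted log2 fold changes of 8.43 for ENSRNOG00000010551 and 6.03 for ENSRNOG00000023340. The fitted value of ENSRNOG00000016149, with 0 reads in TNC, carries no size. The second principal component parted rats R101, R102 and R103 from the others, so both sets were also fitted apart. Within rats R101, R102 and R103 alone 2311 genes differed between the regions, and within rats R104, R105 and R106 alone 2845 did, with 388 against 108 and 356 against 92 genes at 2-fold or more, higher in SC against higher in TNC.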

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

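In this part the slopes by size of difference were chosen only after the result was seen.

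Among 24 sets of 6 values tested for a library far from the others, 2 stood out, where chance gives about 5% of such sets. The TNC library of rat R102 had 15.2% of alignments outside annotated genes, with 12.5% to 13.1% in the other TNC libraries. The SC library of rat R106 had 17536 genes detected, with 17262 to 17364 in the other SC libraries. It was also the deepest library, with 14591508 reads on genes. After thinning to equal totals it had 17288 genes, with 17181 to 17260 in the other SC libraries.

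The 4192 genes that differed between TNC and SC came with fewer reads outside annotated genes in TNC. Of the 32 assignments that exchange the regions within rats, 1, the real one, gave as many genes, and the highest other gave 1 gene. This argues against chance as the source of their number, at the smallest share that 32 assignments allow. The exchanged assignments hold the real difference in their residual variance, which lowers their counts. A difference in depth is argued against, since at least 95.9% of the 4192 genes stayed past the threshold with the same sign in each of 5 thinnings to equal totals. Reads of the kind that fall outside annotated genes remain a candidate source. Rat R102 had the smallest gap in such reads. For differences under 1.5-fold it followed the effect fitted in the other rats with 0.647 of their mean slope (SD of the others 0.145, lowest of the others 0.874). This value lies between the bounds of 0.5 and 0.75, which had been set for the slope over all genes. For differences of 2-fold or more the relative slope of rat R102 was 1.12 (SD of the others 0.131). Over all genes, where large differences weigh more, it was 0.997 (SD of the others 0.121). Both were above the bound of 0.75, which counts against this source for the large differences. The slope over all genes, the one set in advance, thus passed its bound. The bound was not decisive, since the slope over all genes mixes both sizes and R102 was the only rat with a small gap. Anything else particular to this rat enters the slopes. These reasons were not part of the rule set in advance. This source and a difference between the regions themselves, which was not tested otherwise, cannot be told apart.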

How the results depend on the processing

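The counts of differing genes stayed within 1.5 times their value under every alternative except the covariate fit and the fits on 3 rats, which, like thinning to equal totals (4138 genes), were chosen after seeing the data. Over the planned scalings, filters, tools and the fit with no replicate block, 3627 (no replicate block) to 4190 (RLE) genes differed, and no gene of the 4192 changed sign in any of these fits. Without the block, 3598 of the 4192 genes were kept, and no printed gene lost its call. Upper-quartile scaling moved the median log2 difference of all genes from -0.01 to -0.04 and the split to 1754 higher in TNC and 2432 higher in SC. With each rat left out, the counts ranged from 3406 (without rat R103) to 3995 (without rat R102), and those at 2-fold or more from 436 to 491. With the share of alignments outside annotated genes as a covariate beside the replicate block, 64 genes differed, 16 higher in TNC and 48 in SC, 54 by 2-fold or more. Its collinearity with region raised the median standard error from 0.09 to 0.28, and 728 of the 4192 genes changed sign. Beyond that collinearity the cause was not tested. Rats R101 to R103 alone gave 2311 genes, 1113 higher in TNC and 1198 in SC, and rats R104 to R106 alone gave 1503 higher in TNC and 1342 in SC, with fewer samples. The 4 printed genes kept their direction throughout, and 3 lost their call under the covariate alone. The log2 fold change of ENSRNOG00000023340 ranged from 3.37 to 4.39 and that of ENSRNOG00000010551 from 4.43 to 5.43 with a rat left out. The genes bounded within 1.5-fold numbered 8391 to 8704 with a rat left out. Leaving out mitochondrially encoded genes, the oligodendrocyte list as a covariate, and the gene list tests were not run, for want of gene symbols. Fewer genes differed between 1 and 10 CPM (20.5%) than above 100 CPM (48.5%), and whether depth or fewer true differences set this was not tested.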

Other observations

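The patterns in this part were noticed in the data, and the tests of each explanation were set before their own results were seen.

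The excess of SC-enriched genes among differences of 2-fold or more was also present between 10 and 100 CPM, with 78 genes higher in SC and 20 higher in TNC. Above 100 CPM no excess was seen, with 4 genes higher in SC and 4 higher in TNC. Of the genes with such differences and a mean of at least 10 CPM, 82 were higher in SC, or 77.4% (exact binomial interval 68.2% to 84.9%). For genes between 10 and 100 CPM this argues against loss of weakly expressed genes from the TNC libraries as the whole cause. The lowest SC share under RLE or upper-quartile scaling was 82.3%, so the excess did not depend on the choice among these scalings. They moved the median log2 difference little, to -0.0049 with RLE and -0.036 with upper quartile from -0.0053 with TMM. The test therefore could not show whether a larger error of scaling contributes. A biological difference between the regions and a difference in the cells captured with them stay open and were not tested, since no gene could be named.

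Expression varied more between rats in TNC than in SC: the variance of log2 CPM was larger in TNC for 57.8% of genes, with a median variance ratio of 1.23, and of the 32 exchanges of regions within rats only the real assignment gave as large a ratio in either direction (exact permutation p = 0.0312, two-sided, the smallest possible). Counting noise from lower depth is argued against, since among 2543 genes with a mean of at least 1000 reads the median log2 ratio was 0.56, against 0.29 over all genes. A single deviating rat is argued against, since the median log2 ratio over all genes was at least 0.25 without any 1 rat. Leaving out 1 rat does not address a division into sets of rats, which stays open: on the second principal component the TNC libraries spanned -29.6 to 22.7, with rats R101 to R103 below 0 and the others above, and the SC libraries -12.9 to 4.21. A candidate explanation is that the captured TNC pieces differed in how far they resembled SC. Slopes of single libraries along the difference between SC and TNC, fitted without the rat in question, ranged from -0.195 (rat R105) to 0.0703 (rat R101) in TNC and from -0.0115 to 0.138 in SC, an SD ratio of 1.89 that falls short of the ratio of 2 set in advance, so this stays open.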
